A study of Rattus norvegicus with 4 samples.

How the data were processed

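Single-cell RNA sequencing was done on gingiva from around the maxillary left second molars of Sprague-Dawley rats in a 2 by 2 design: normoglycaemic or streptozotocin-diabetic, without or with ligature-induced periodontitis. Per the labels each library pooled gingiva of 9 rats, diabetes meant a blood glucose of at least 250 mg/dl 7 days after streptozotocin, and tissue was digested with collagenase and trypsin before droplet capture with the 10x Chromium 3' chemistry. The deposited values are counts: per the file headers, UMIs per gene and cell barcode written by Cell Ranger 5.0.0, not normalised. The submitters' processing notes also name STAR, without a version, and Seurat 3.1.1, and give the mouse build mm10, whereas the identifiers in the files are rat Ensembl genes, so genes were read by those rat identifiers and symbols. Every barcode in the files has at least 500 UMIs, and other upstream filters are not stated.

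Depth per library, in the order control, periodontitis, diabetic and diabetic periodontitis, was 206012073, 210621226, 194778513 and 219348078 UMIs over 15064, 13924, 15260 and 10276 barcodes. Median UMIs per barcode were 9585, 11082, 9637 and 18231, and median mitochondrial shares 4.09%, 3.46%, 5.90% and 4.51%. Barcodes with at least 200 genes, at least 500 UMIs and under 20% mitochondrial UMIs were kept, which left 14188, 12963, 14341 and 9334 cells. Doublets were scored per library after the Scrublet scheme, with 2 simulated doublets per cell and exact neighbours from scikit-learn 1.9.0 on variable genes chosen with scanpy 1.11.5. Its automatic threshold called between 0.0107% and 2.12% of cells depending on the library, so after those calls were seen the highest-scoring cells were removed at an expected rate of 0.8% per 1000 cells instead. This removed 1555, 1333, 1585 and 696 cells and left 45657 for analysis.

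Cells of the 4 libraries were clustered together on 2000 variable genes, 30 principal components and 15 neighbours with the Leiden method at resolution 1 (leidenalg 0.10.2, igraph 0.11.9), without correction between libraries, which gave 40 clusters. Markers of each class were fixed before the data were examined. A class was a candidate for a cluster if at least 3 of its markers were detected in at least 10% of the cells. The cluster took the candidate whose markers had the highest mean level, standardised across clusters. Macrophage, monocyte and dendritic cells fell into 1 cluster and were merged as myeloid. After the data were seen, 4 clusters with markers of epithelial cells and of another class together with many UMIs were left unnamed (7.27%, 0.860%, 0% and 0.0463% of the libraries), as was 1 cluster with few UMIs (3.43%, 4.03%, 2.73% and 4.11%). Of 37 clusters with at least 20 cells, 11 took at least 75% of their cells from 1 library, so epithelial cells were compared only within clusters with at least 150 cells in every library. A compared cluster also needed a median of at least 0.5 of the library's median UMIs per cell, which left out cluster 12 (0.367). A gene among the 10 that define a cluster was not compared singly in the results within that cluster's class or, for epithelial cells, within that cluster (genes that define other epithelial clusters, such as S100a8, S100a9, Krt13 and Ada, were), but such genes stay in the lists (5 of 6 for MHC class II in myeloid cells) and C1qtnf9, which defines an endothelial cluster, is given among the reversals. Cluster sizes are given only to show what a class is made of. Neutrophil gene levels are given only for the pairs with enough cells, since the control library has 21 neutrophils.

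A library is the replicate, so n = 1 per group and no test was run. Shares have exact Clopper-Pearson intervals. For gene levels, UMIs were summed over the cells of a class and library and scaled to the class's total (CPM), with exact Poisson intervals and exact conditional intervals for ratios, all at 95% and covering counting error only. Levels were computed in classes with at least 50 cells. Named genes were chosen by a rule fixed before the data were examined: per class and comparison, with at least 100 cells in both libraries, the 2 highest and 2 lowest log2 ratios of CPM + 10 among genes with at least 100 UMIs over the pair, at least 100 CPM in 1 of the libraries and at least 20% of the highest level in any other class of that library. As applied, only other classes with at least 20 cells in the library counted, a minimum added after the rule was fixed, and 4 of the 124 genes it names (Krt13 in epithelial clusters 0 and 1, 5S_rRNA in cluster 1 and Abi3bp in cluster 10, all for diabetes with periodontitis) would not pass with classes of any size. Other genes named are members of the lists, picked after their values were seen. A gene with 0 UMIs is compared with a floor of 3 UMIs.

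For 35 gene lists, fixed before the data were examined, the median log2 ratio was taken over genes with at least 50 UMIs in the pair, where at least 5 genes passed, and set against 10000 random lists of equal size matched on mean expression. Its percentile describes these libraries and carries no p-value. Genes counted as higher or lower differ by at least 1.5-fold. Of 621 list and marker symbols 572 were found in the files. The share of T cells with a UMI of a gene was taken after thinning every cell to 1000 UMIs, with fibroblasts as background.

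The calculations were checked on simulated data: counts were redrawn from the mean profile of both libraries at each library's depth for fibroblasts, blood endothelial cells and epithelial cluster 0 in all 4 comparisons, with 67 genes changed 1.5-fold, 67 changed 2-fold and 66 changed 4-fold. For fibroblasts the direction was right for 98.5%, 100%, 97.0% and 94.0% of the genes changed 1.5-fold in periodontitis in normoglycaemic rats, periodontitis in diabetic rats, diabetes without and diabetes with periodontitis, and for 100% of genes changed 2-fold or 4-fold. Intervals held the true ratio for 95.2%, 95.8%, 95.7% and 95.9% of unchanged genes, of 10159, 3181, 9555 and 7590 genes with enough UMIs. The simulated counts were Poisson draws, which is also the model of the intervals. Spread between cells or rats was not simulated, so the check covers the calculation only. A planted list of 20 genes at 2-fold came out at percentile 100 in every comparison, and lists of unchanged genes at mean percentiles of 49.2, 47.8, 41.9 and 41.5. Blood endothelial cells had the right direction for 98.5%, 98.5%, 100% and 100% of genes changed 1.5-fold and epithelial cluster 0 for 100%, 100%, 100% and 98.5%.

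The alternatives fixed before the data were examined were a stricter cell filter (500 genes, 1000 UMIs, 10% mitochondrial), doublets kept, resolution 0.5 and 2, genes centred within each library before the principal components, median-of-ratios size factors, a pseudocount of 1 CPM, no filter on low counts or at least 200 UMIs, cells thinned to 1000 UMIs, cells weighted equally, and 10% of a class's UMIs subtracted as free RNA. The free RNA profile was the summed UMIs of all analysed cells of the library, and negative values were set to 0. Added after seeing the data were T cell shares without thinning and single clusters with at least 25 cells in both libraries. Those run were cluster 6 (blood endothelial), cluster 24 (mural) and clusters 7, 17 and 20 (fibroblast). Mural cluster 25, with 204, 132 and 76 cells in the control, periodontitis and diabetic libraries, was not run alone. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-image 0.26.0 and matplotlib 3.10.9 were used, with a random seed of 1.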

Results

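Gingiva around the maxillary left second molar of normoglycaemic and streptozotocin-diabetic rats, with or without ligature-induced periodontitis, was compared cell class by cell class. Each of the 4 groups was 1 library from a pool of 9 rats: the control library (normoglycaemic, no periodontitis), the periodontitis library, the diabetic library and the diabetic periodontitis library. With 1 library per group the spread between rats was not measured and nothing was tested. Every value below describes these 4 libraries, and each range in parentheses is a 95% interval that covers counting error only. Leukocytes made up 1.27% (1.08 to 1.48) of 12633 control cells, 2.46% (2.19 to 2.76) of 11630 periodontitis cells, 2.06% (1.82 to 2.32) of 12756 diabetic cells and 7.19% (6.65 to 7.75) of 8638 diabetic periodontitis cells. Fibroblasts made up 15.5%, 10.04%, 2.23% and 0.579% of the same libraries. Of the 35 gene lists fixed before the data were examined, those described were picked for their size after their values were seen. Recomputing 109 of the list medians under other settings gave 1330 values, of which 456 moved beyond their counting interval and 25 changed sign.

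**Figure D1:**
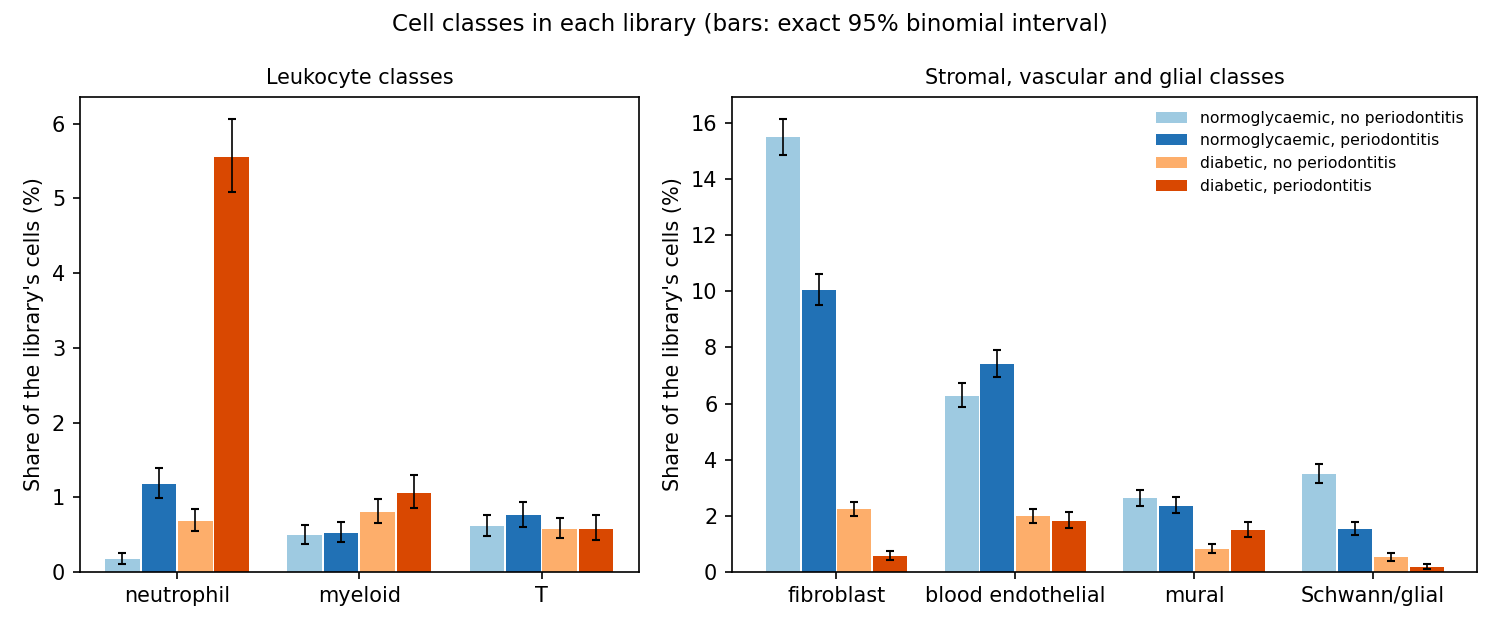
Bars give the share of each library's cells (%) in 7 named classes, with exact 95% binomial intervals, for the 4 libraries. Neutrophils reached 5.56% in the diabetic periodontitis library, and fibroblasts were 15.5% of the control library but 2.23% of the diabetic library.

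Periodontitis in normoglycaemic rats came with more neutrophils, a smaller fibroblast share and a mural class with more matrix transcripts. Neutrophils were 0.166% of control cells (21 cells) and 1.18% of periodontitis cells (137 cells), a ratio of 7.09 (4.46 to 11.8). T cells were 0.610% and 0.757%, and the merged macrophage, monocyte and dendritic class (called myeloid here) 0.491% and 0.525%, ratios whose intervals include 1. The T cell ratio depended on the setting: it was 2.24 (1.38 to 3.74) under a stricter cell filter, 2.23 (1.47 to 3.45) at a finer clustering and 2.41 (1.64 to 3.59) with doublets kept, and the control T class included cells with epithelial transcripts. The fibroblast share was 1.54-fold lower (1.43 to 1.66) and the Schwann and glial share 2.30-fold lower (1.93 to 2.75), while the blood endothelial ratio was 1.18 (1.07 to 1.30), but 0.912 (0.815 to 1.02) under the stricter filter, 1.07 (0.963 to 1.19) at the finer clustering and 1.02 (0.934 to 1.11) with doublets kept. Neutrophils had a median of 0.112 of the library's median UMIs per cell, so the minimum of 500 UMIs can set their share. Clusters that carried epithelial and other markers together were left unnamed and held 7.27% of control cells against 0.860% of periodontitis cells, so shares near that size can depend on how they are assigned.

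Blood endothelial cells of the periodontitis library carried Glycam1, which encodes an L-selectin ligand of high endothelial venules, at 452 CPM (UMIs of a gene scaled to the total of the class) against 7.15 CPM in the control library, a 63.3-fold difference (41.3 to 103). The ubiquitin-like gene Ubd was 4.11-fold higher (3.27 to 5.19) and the leukocyte adhesion gene Icam1 1.23-fold higher (1.14 to 1.32), whereas Nebl was 2.38-fold and Rbp7 2.19-fold lower. The NF-kB targets list had a median log2 ratio of 0.29 (0.19 to 0.38) in these cells. Lists of other cell types included larger medians, 0.50 (0.31 to 0.74) for neutrophil granule and activation and -0.67 (-0.79 to -0.46) for pericyte and contractile. That of epithelial wound and defence was smaller, at 0.13. The interferon response list had a median of -0.07 (-0.13 to 0.01), and Isg15 stood at 331 CPM and 351 CPM. In mural cells the collagen and matrix list had a median of 0.80 (0.65 to 0.90), with 12 of 21 genes at least 1.5-fold higher and 1 lower, above all of 10000 random lists matched on expression. Postn was 10.4-fold higher there (5.57 to 21.4), Col1a1 3.74-fold (3.42 to 4.10) and Timp1 2.47-fold (2.20 to 2.78), and the protease inhibitors list had a median of 0.70. Mmp9 stood at 132 CPM against 3.62 CPM in mural cells, and Tnnt2 was 7.71-fold higher, while Ccl7 was 6.47-fold and Steap4 2.45-fold lower. Mmp9 is also a neutrophil marker, and the neutrophil granule and activation list had a median of 0.61 (0.43 to 0.80) in these mural cells. Whether RNA from neutrophils added to the Mmp9 level was not tested. Mural cluster 24 alone, which excludes the contractile cluster 25, had a collagen and matrix median of 0.46.

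Fibroblasts of the periodontitis library had 888 CPM of the monocyte chemokine gene Ccl2 against 302 CPM, and Postn at 1690 CPM against 838 CPM. Postn was lower in cluster 20 alone. Myoc was 5.12-fold higher (4.87 to 5.39), and Ecm1 2.35-fold and Igfbp6 2.29-fold lower. The dissociation and immediate early list had medians of 0.24 (0.23 to 0.28) in fibroblasts, -0.05 in blood endothelial cells, -0.10 in mural cells and -0.10 in myeloid cells. Over the whole collagen and matrix list the fibroblast median was 0.03 (-0.02 to 0.08), at percentile 47.7 of the random lists, with 2 of 21 genes at least 1.5-fold higher and 1 lower. Myeloid cells of the periodontitis library had less of the resident macrophage genes: C1qa stood at 671 CPM against 2134 CPM and Mrc1 at 37.0 CPM against 292 CPM. The complement list had a median of -1.65 in this class with all 5 genes lower, and the macrophage resident and repair list a median of -1.91. The cytokines and chemokines list had a median of -0.84 (-0.98 to -0.53), with 8 of 13 genes at least 1.5-fold lower and 1 higher. Cxcl2 was 0.414 of its control level (0.372 to 0.459) and Il1b 1.12-fold (0.926 to 1.35). The MHC class II list, 5 of whose 6 genes are among those that define the merged cluster, had a median of 0.47 (0.39 to 0.53), so the levels of this class can depend on its mix of macrophages and dendritic cells. With 62 and 61 cells these medians rest on few cells, and under a stricter cell filter the medians were -0.613 for complement, -0.804 for the macrophage resident and repair list and -0.18 for cytokines and chemokines. The cytokines and chemokines median was -0.28 with doublets kept, -0.33 with cells thinned and -0.059 with no filter on low counts.

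Epithelial cells were compared cluster by cluster, because an epithelial cluster mostly from the diabetic periodontitis library was itself defined by S100a8 and S100a9. Cluster 10, marked by the junctional epithelium genes Fdcsp and Odam, had S100a9 at 3646 CPM in the periodontitis library against 399 CPM in the control library, 9.13-fold higher (8.72 to 9.57). S100a8 was 2.64-fold higher (2.57 to 2.71) and the neutrophil chemokine gene Cxcl1 1.71-fold higher (1.62 to 1.81). S100a9 stood at 38.6 CPM in blood endothelial cells and 19.3 CPM in fibroblasts of the periodontitis library, the level at which free RNA can be expected in any cell. Fam25a was 2.78-fold lower in cluster 10. Scgb1a1 was 39.9-fold higher, a direction that reversed at a finer clustering. The epithelial wound and defence list had medians of 0.21 in cluster 0, 0.19 in cluster 1, 0.33 in the cycling cluster 2, 0.16 in the suprabasal cluster 3 and 0.29 in cluster 10. With no filter on low counts the median of cluster 2 reversed to -0.0003, and with 10% free RNA subtracted those of clusters 0 and 2 were 0, that of cluster 1 was 0.027 and that of cluster 3 was 0.0061. A gene that the subtraction set to 0 in both libraries has a log2 ratio of 0. The medians after subtraction therefore show neither that the differences are absent nor that they are free RNA. In cluster 3 Krt13 was 2.41-fold and Phlda1 1.77-fold higher. Cldn4 was 1.95-fold and Serpinb2 1.65-fold higher in cluster 2, Ly6d 1.59-fold and Ctsc 1.51-fold higher in cluster 1, and Abcc5 1.54-fold and F3 1.53-fold higher in cluster 0. Tomm6 was lower in clusters 0, 1, 2 and 3, by 2.20-fold to 2.44-fold.

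Periodontitis in diabetic rats came with neutrophils at 5.56% of cells (480 cells) against 0.682% (87 cells), a ratio of 8.15 (6.47 to 10.4), and a leukocyte share 3.49-fold higher (3.01 to 4.04). Fibroblasts were 3.85-fold lower (2.84 to 5.31), with only 50 cells left in the diabetic periodontitis library, and Schwann and glial cells were 3.19-fold lower (1.77 to 6.16), or 15.6-fold (2.53 to 642) under the stricter filter, which left 1 such cell. Mural cells were 1.83-fold higher (1.40 to 2.39). The shares of blood endothelial, myeloid and T cells had ratios of 0.926, 1.30 and 1.01, with intervals that include 1. The blood endothelial ratio was 0.660 (0.514 to 0.842) under the stricter filter and 0.727 (0.581 to 0.905) at the finer clustering, and the myeloid ratio 1.503 (1.18 to 1.92) with doublets kept. The diabetic periodontitis library was the deepest, with a median of 18231 UMIs per barcode against 9637 in the diabetic library.

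Mural cells of the diabetic periodontitis library had a collagen and matrix median of 2.11 (1.81 to 2.19), with 17 of 19 genes at least 1.5-fold higher and 2 lower. Col1a1 stood at 5675 CPM against 457 CPM and Postn at 1127 CPM against 33.3 CPM, 12.4-fold (10.9 to 14.2) and 33.9-fold (20.8 to 59.4). The matrix proteases list had a median of 1.55 and the protease inhibitors list of 1.78, with the stromelysin gene Mmp3 63.2-fold higher (24.6 to 233) and Timp1 8.61-fold higher (7.27 to 10.3). Col15a1 had 842 UMIs against 1 UMI, a ratio of 268 (48.1 to 10617). Dgkb was 22.9-fold and Pcp4l1 20.9-fold lower. Contractile cluster 25 held 76 of 105 mural cells in the diabetic library but 6 of 130 in the diabetic periodontitis library, and in cluster 24 alone the medians were 1.00 for collagen and matrix, 0.60 for matrix proteases and 1.06 for protease inhibitors.

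In fibroblasts of diabetic rats the collagen and matrix list was higher with periodontitis, with a median of 0.98 (0.84 to 1.12) above all random lists and 13 of 21 genes at least 1.5-fold higher against 2 lower. Postn was 2.61-fold higher (2.41 to 2.83). Acta2, which marks contractile cells, had 102 UMIs against 6 UMIs and was 50.7-fold higher (22.5 to 141), and the pericyte and contractile list had a median of 3.08 with all 6 genes higher. Lower lists were cytokines and chemokines (median -1.61), interferon response (-1.20) and insulin and IGF (-0.92, with 11 of 15 genes at least 1.5-fold lower). Cxcl12 was 0.216 and Igf1 0.258 of the level without periodontitis. Cluster 20 held 241 of 284 fibroblasts in the diabetic library and 12 of 50 in the diabetic periodontitis library. The dissociation and immediate early list was lower too, with medians of -1.19 in fibroblasts, -0.66 in blood endothelial cells, -0.53 in mural cells and -0.92 in myeloid cells, and Fos in fibroblasts was 0.393 of its level. The mural median was -0.21 in cluster 24 alone. The gene levels of stromal and myeloid cells in this pair of libraries therefore stand beside a difference in dissociation genes.

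Blood endothelial cells of the diabetic periodontitis library had less interferon response transcript than those of the diabetic library, with a list median of -0.54 (-0.76 to -0.37) and 8 of 18 genes at least 1.5-fold lower against 0 higher. The chemokine gene Cxcl10 was 0.324 (0.250 to 0.415) and Ifit3 0.315 (0.198 to 0.488) of its level. Isg15 was at 52.4 CPM and 51.9 CPM, a ratio of 0.991. The NF-kB targets list had a median of 0.34 (0.24 to 0.55), and Icam1 was 1.16-fold higher (1.04 to 1.29), though not in cluster 6 alone. Vwa1, a matrix protein gene, was 8.81-fold higher (7.43 to 10.5) and the keratinocyte gene Krt1 11.7-fold higher. Lists of other cell types had larger medians in these endothelial cells, 1.89 (1.62 to 2.19) for epithelial wound and defence and 1.68 (1.34 to 1.91) for neutrophil granule and activation, which were 0.738 and 0.127 once 10% free RNA was subtracted.

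Myeloid cells of diabetic rats had 1374 CPM of Il1b with periodontitis against 524 CPM without, 2.62-fold higher (2.28 to 3.02), and Nos2 9.58-fold (5.68 to 17.4), Ccl3 2.40-fold (2.02 to 2.88) and Ldha 3.49-fold (3.06 to 3.99) higher. Nos2, one of the genes that define the neutrophil cluster, stood at 298 CPM in these myeloid cells and 1799 CPM in neutrophils of the same library, where Il1b was at 6330 CPM and Ccl3 at 3337 CPM, so RNA from neutrophils can add to these ratios as their share grows. The macrophage inflammatory list had a median of 1.31, with 5 of 8 genes at least 1.5-fold higher and 0 lower, and the glycolysis list a median of 1.34, with 10 of 11 higher. The macrophage inflammatory list includes Il1b, and also Nos2, Trem1 and Clec4e, which define the neutrophil cluster. RNA from neutrophils can therefore add to its median too. NF-kB targets had a median of 0.68. Complement, with a median of -1.58, and the macrophage resident and repair list, with -1.85, were lower as in normoglycaemic rats, and C1qa was 0.375 (0.309 to 0.452) and Mrc1 0.321 (0.195 to 0.517) of its level. Cytokines and chemokines as a list had a median of 0.30 (0.20 to 0.73), at percentile 90.1 of the random lists, but 0.084 with no filter on low counts and 1.24 with at least 200 UMIs per gene. With doublets kept the NF-kB targets median was 0.24.

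Epithelial cluster 10 of diabetic rats also had more S100a9 with periodontitis, 1998 CPM against 165 CPM or 12.1-fold (11.5 to 12.8), and S100a8 was 3.86-fold (3.72 to 4.01), Cxcl1 2.43-fold (2.30 to 2.56) and the wound keratin gene Krt16 6.17-fold (5.80 to 6.57) higher. S100a9 in blood endothelial cells of the diabetic periodontitis library stood at 126 CPM. Cluster 10 had medians of 1.22 for the epithelial wound and defence list, 1.10 for neutrophil granule and activation genes against 1.17 for periodontitis in normoglycaemic rats, 0.47 (0.42 to 0.51) for cytokines and chemokines, and -0.40 for interferon response. The dissociation and immediate early list had a median of 0.54 (0.46 to 0.65) in cluster 10, so its levels too stand beside a difference in dissociation genes. In clusters 0, 1, 2 and 3 the dissociation medians were 0.09, -0.40, 0.23 and -0.28. The epithelial wound and defence list had a median of 0.95 in cluster 3, where Sprr1b was 3.79-fold higher and Krt13 6.40-fold higher, the latter reversing under a stricter cell filter. That list's median was 0.41 in cluster 10 at the finer clustering and 0.02 in cluster 3 with free RNA subtracted. Clusters 0, 1 and 2 had medians of 0.30, 0.27 and 0.37 for this list, but in clusters 1 and 2 its sign reversed once 10% free RNA was subtracted, as did that of Krt16 in clusters 0 and 2. Cldn4 was 2.10-fold higher in cluster 2 and Nrg1 1.69-fold higher in cluster 0.

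Diabetes without periodontitis came with a stromal and vascular share of 5.66% (5.27 to 6.08) against 28.4% (27.6 to 29.2), 5.02-fold lower (4.63 to 5.45). Fibroblasts were 6.96-fold lower (6.14 to 7.91), Schwann and glial cells 6.76-fold (5.21 to 8.90), mural cells 3.19-fold (2.56 to 4.02) and blood endothelial cells 3.18-fold (2.76 to 3.68). The leukocyte share was 1.63-fold higher (1.33 to 1.99), the neutrophil share 4.10-fold (2.52 to 6.96) and the myeloid share 1.65-fold (1.19 to 2.29). The myeloid ratio was 0.972 (0.729 to 1.30) under the stricter filter and 1.12 (0.871 to 1.44) with doublets kept. Lymphatic endothelial cells numbered 66 in the control library and 15 in the diabetic library, 4.44-fold lower as a share (2.51 to 8.38).

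Interferon genes were lower in the vessels of the diabetic library. Isg15 in blood endothelial cells stood at 52.4 CPM against 331 CPM, 6.32-fold lower (4.996 to 8.11), and Ifit3, Cxcl10 and Irf7 were 0.421, 0.417 and 0.460 of their control level. The interferon response median was -0.81 (-0.99 to -0.69), below all random lists, with 17 of 25 genes at least 1.5-fold lower and 1 higher, and it was -0.93 in endothelial cluster 6 alone but -0.34 with doublets kept. Manba was 5.58-fold lower. Mural cells had an interferon response median of -0.99 (-1.25 to -0.68), or -0.19 with doublets kept and -1.30 in cluster 24 alone, with 8 of 11 genes lower, Isg15 at 0.324 (0.206 to 0.489) of its control level and Cxcl10 10.9-fold lower (6.16 to 21.2). Cluster 24 held 29 of the 105 diabetic mural cells, and contractile cluster 25, which held 76, was not run alone. Fhad1 was 10.2-fold higher and Bbs4 12.1-fold lower in mural cells. Epithelial cluster 0 had a smaller median of -0.20 (-0.27 to -0.15), and Ifi27 was 0.514 of its level there. Fibroblasts had a median of 0.30, which was -0.26 in cluster 20 alone.

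**Figure D2:**
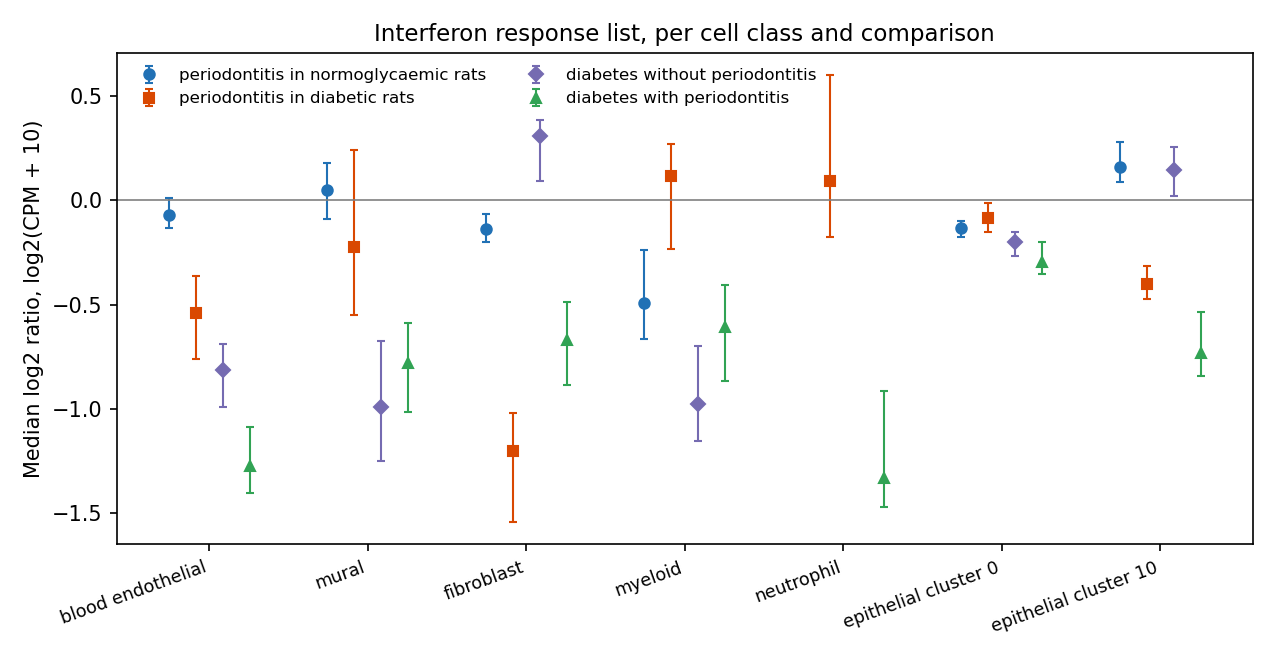
Points give the median log2 ratio of the interferon response list for each cell class and comparison, with 95% counting intervals. Blood endothelial cells sit at -0.81 for diabetes without periodontitis, at -1.27 for diabetes with periodontitis and at -0.07 for periodontitis in normoglycaemic rats.

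Fibroblasts of the diabetic library had 981 CPM of the chemokine gene Cxcl12 against 96.4 CPM, 10.2-fold higher (9.40 to 11.03), with Il6 9.44-fold (7.78 to 11.4) and Ccl2 3.83-fold (3.61 to 4.07) higher. The cytokines and chemokines list had a median of 1.66, with 12 of 15 genes higher and 2 lower. Cluster 20 held 241 of 284 diabetic fibroblasts but 238 of 1957 control fibroblasts, and within cluster 20 alone that median was 0.32, with log2 ratios of 0.864 for Cxcl12, 1.49 for Il6 and 0.119 for Ccl2. Myoc was 13.5-fold (8.49 to 22.7) and C1qtnf3 8.52-fold (6.68 to 11.04) lower, and the TGF-beta list had a median of -0.68, which was -0.18 in cluster 20 alone. The dissociation and immediate early median was 0.44 in these fibroblasts, and 0.28 in cluster 20 alone. The collagen and matrix median was -0.21 (-0.29 to -0.09), at percentile 11.4, but -0.70 with doublets kept and 0.07 in cluster 20 alone. In myeloid cells C1qa was 0.298 (0.261 to 0.340) of its control level, the complement list had a median of -1.73 and the macrophage resident and repair list of -1.49. Under the stricter filter the log2 ratio of C1qa was -0.0761 and these medians were -0.0693 and -0.117. The cytokines and chemokines median was -1.37 (-1.52 to -1.09) in myeloid cells, with 7 of 12 genes lower and 2 higher, but 0.02 under the stricter cell filter. Mrc1 at 0.390 and Cxcl2 at 0.419 of their control level also reversed under that filter and with doublets kept.

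Epithelial cluster 10 of the diabetic library had more cycling genes and fewer differentiation genes than that of the control library. Mki67 stood at 120 CPM against 49.9 CPM, 2.40-fold higher (2.10 to 2.76), and the G2M phase and S phase lists had medians of 0.79 and 0.78. At the finer clustering these medians were 0.201 and 0.449, and the log2 ratio of Mki67 was 0.269. The epithelial basal list had a median of 0.53, whereas the epithelial cornified list had a median of -1.01 with 10 of 14 genes lower, Krtdap at 0.439 of its level and Sbsn 4.39-fold lower. Krt10 was 0.348 of its level, a direction that reversed with doublets kept. The epithelial wound and defence list had a median of -1.03, with S100a8 at 0.237 (0.228 to 0.247) and Krt16 6.74-fold lower, and the cytokines and chemokines list had a median of -0.92. At the finer clustering the medians were -0.36 for wound and defence and -0.01 for cytokines and chemokines, and with doublets kept -0.17 for epithelial cornified. Cxcl1 was 0.476 of its level, which reversed at a finer clustering. Pappa1 was 5.76-fold higher (4.66 to 7.20). The dissociation and immediate early median was -0.67 in cluster 10, reversing at the finer clustering and with doublets kept, and -0.40 in cluster 3. In cluster 3 Krt36 was 140-fold lower (81.8 to 263) and the dendritic cell chemokine gene Ccl20 3.57-fold lower (3.46 to 3.69). Dnajb1 was 2.34-fold and Krt42 2.38-fold lower in cluster 0, and Gadd45g 2.24-fold and Ifi27 2.13-fold lower in cluster 1. The clock output gene Dbp was 5.82-fold higher (5.21 to 6.53) in cluster 0. Ada was higher in clusters 0, 1, 2 and 3, at 45.2-fold to 57.3-fold, and Krt13 16.0-fold higher in cluster 0. The 175 CPM of Ada in cluster 0 lay below its level in all 7 classes that are not epithelial (215 to 604 CPM), and the 289 CPM of Krt13 lay near theirs (284 to 856 CPM). 5S_rRNA, 7.36-fold, 10.2-fold, 8.73-fold and 5.89-fold higher in clusters 1, 2, 3 and 10, was at 59.8 to 393 CPM in those classes.

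Diabetes with periodontitis came with a fibroblast share 17.4-fold lower (13.1 to 23.5), a blood endothelial share 4.05-fold lower (3.42 to 4.83) and a Schwann and glial share 9.39-fold lower (5.45 to 17.5) than in the periodontitis library. The last was 46.9-fold (8.10 to 1883) under the stricter filter, from 1 cell. Mural cells were 1.57-fold lower (1.27 to 1.95). Neutrophils were 4.72-fold higher (3.89 to 5.75), myeloid cells 2.01-fold (1.44 to 2.83) and all leukocytes 2.92-fold (2.54 to 3.37), while the T cell ratio of 0.765 (0.529 to 1.09) includes 1. Lymphatic endothelial cells numbered 4 and 3.

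Interferon genes were lower in blood endothelial cells of the diabetic periodontitis library than in those of the periodontitis library. The interferon response list had a median of -1.27 (-1.40 to -1.09), below all random lists, with 22 of 25 genes at least 1.5-fold lower and 0 higher, and ranged from -1.69 with a pseudocount of 1 CPM to -0.72 with doublets kept. Cxcl10 was 8.25-fold lower (6.61 to 10.4), and Isg15 was 0.148 (0.114 to 0.189), Ifit3 0.141 (0.0917 to 0.207) and Irf7 0.261 (0.179 to 0.370) of the level in the periodontitis library. Glycam1 had 0 UMIs against 1595 UMIs and was at least 194-fold lower, for a floor of 3 UMIs. Krt1 was 9.43-fold higher, and Krt10 4.47-fold higher with a sign that reversed in 3 settings. The interferon response median was -0.78 (-1.01 to -0.59) in mural cells, or -1.299 in cluster 24 alone, with Isg15 at 0.192 of its level, -0.61 in myeloid cells, -0.67 in fibroblasts, -0.29 in epithelial cluster 0 with Ifi27 at 0.564, and -0.73 in epithelial cluster 10. Neutrophils had an interferon response median of -1.33 (-1.47 to -0.91), with Isg15 at 1034 CPM against 2871 CPM and Irf7 4.75-fold lower (3.44 to 6.57).

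Neutrophils of the diabetic periodontitis library had Lcn2, which encodes a siderophore-binding granule protein, 10.6-fold higher (7.82 to 14.9). The neutrophil granule and activation list had a median of 0.47 and the cytokines and chemokines list of -0.76 with 7 of 12 genes lower, Cxcl2 being 0.429 of its level (0.413 to 0.445). In myeloid cells Ccl3 was 11.6-fold (8.21 to 16.9), Nos2 9.04-fold (5.44 to 16.1), Ldha 4.14-fold (3.60 to 4.78) and Il1b 2.46-fold (2.15 to 2.82) higher. The macrophage inflammatory list had a median of 1.56 with 7 of 8 genes higher, glycolysis 1.06 with 9 of 11 higher, NF-kB targets 0.47 and cytokines and chemokines 0.32 (0.17 to 0.47), at percentile 92.7. The last was 0 with no filter on low counts, 0.048 with cells thinned, 0.99 under the stricter filter and 1.28 with at least 200 UMIs per gene, and NF-kB targets was 0.10 with at least 200 UMIs. RNA from neutrophils can add to the Nos2, Ccl3 and Il1b ratios and to the macrophage inflammatory median of myeloid cells here too.

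Mural cells had a collagen and matrix median of 1.06 (0.96 to 1.17), with 16 of 20 genes higher and 2 lower, and of 0.57 in cluster 24 alone. Contractile cluster 25 held 132 mural cells of the periodontitis library and 6 of the diabetic periodontitis library. Mmp3 was 93.5-fold (49.0 to 205), Postn 16.4-fold (13.5 to 20.1) and Col1a1 4.19-fold (3.99 to 4.39) higher, the matrix proteases list had a median of 0.53, or 0.13 in cluster 24 alone, and Pcp4l1 was 12.8-fold lower. Fibroblasts had a collagen and matrix median of 0.61 (0.57 to 0.76), with 11 of 21 genes higher and 3 lower, Fn1 3.27-fold higher (3.03 to 3.52) and a pericyte and contractile median of 1.56. In cluster 17 alone, with 29 fibroblasts of the diabetic periodontitis library, the collagen and matrix median was 0.26. The dissociation and immediate early list had medians of -1.02 in fibroblasts, -0.53 in blood endothelial cells, -0.57 in mural cells (-0.26 in cluster 24 alone), -0.85 in myeloid cells and -0.63 in epithelial cluster 3, and Fos was 0.439 of its level in fibroblasts.

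Epithelial cluster 10 again had more cycling and fewer cornified transcripts with diabetes. The G2M phase list had a median of 1.23 with 13 of 14 genes higher, S phase 0.72, epithelial basal 0.54, and epithelial cornified -1.08 with 12 of 14 genes lower. At the finer clustering the medians were 0.94, 0.48, 0.046 and -0.48, and with doublets kept 0.52, 0.54, 0.31 and -0.47. Mki67 was 2.89-fold higher (2.43 to 3.45), Krtdap was 0.228 and Krt10 0.155 of its level, and Krt24 was 22.2-fold lower. The epithelial wound and defence median was -0.75, or -0.13 at the finer clustering, S100a8 was 0.348 of its level and Scgb1a1 19.3-fold lower, and the directions of both genes reversed at a finer clustering. These values leave out the epithelial clusters that were not compared. Among those, cluster 4, defined by S100a8 and S100a9, held 509 periodontitis and 1897 diabetic periodontitis cells, and cluster 8 held 116 and 1553. Cluster 10 held 318 of the 7303 epithelial cells of the diabetic periodontitis library. Pappa1 was 9.01-fold and Abi3bp 7.55-fold higher, the latter at 119 CPM, below its 152 CPM in another class of that library and its 1898 CPM in 3 lymphatic endothelial cells. In cluster 3 Krt13 was 7.93-fold higher, Ccl20 3.75-fold and Dnajb1 2.97-fold lower, and Serpinb12 3.90-fold higher with a reversal at a finer clustering. Cluster 2 had Hist2h2ac 5.20-fold and Tomm6 3.64-fold higher. Dbp was 12.1-fold higher in cluster 0 (10.2 to 14.4), where Krt13 was 5.24-fold higher, but at 165 CPM no higher than its level in the classes that are not epithelial (172 to 756.1 CPM), Krt24 3.05-fold lower and Krt42 4.32-fold lower, the last reversing at a finer clustering.

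The share of T cells with a UMI of Il17a, a cytokine gene of type 17 T cells, was higher with periodontitis in both pairs of libraries. After each cell was thinned to 1000 UMIs it was 6.67% (5 of 75 cells, 2.20 to 14.9) in the control library and 25.6% (21 of 82, 16.6 to 36.4) in the periodontitis library. In diabetic rats it was 8.57% (6 of 70, 3.21 to 17.7) without and 29.2% (14 of 48, 16.95 to 44.1) with periodontitis. Fibroblasts as background had 1 of 1935, 0 of 1104, 0 of 277 and 0 of 46 cells, which for the zeros allows up to 0.334%, 1.32% and 7.71%. Median UMIs per cell before thinning were 4121, 3648.5, 3389 and 4037.5 in T cells and 5405, 5611, 4371 and 7999.5 in fibroblasts. The T class of the control library included cells with epithelial transcripts: at a finer clustering it held 35 T cells, and the shares were 8.82%, 33.3%, 9.09% and 29.5%.

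**Figure D3:**
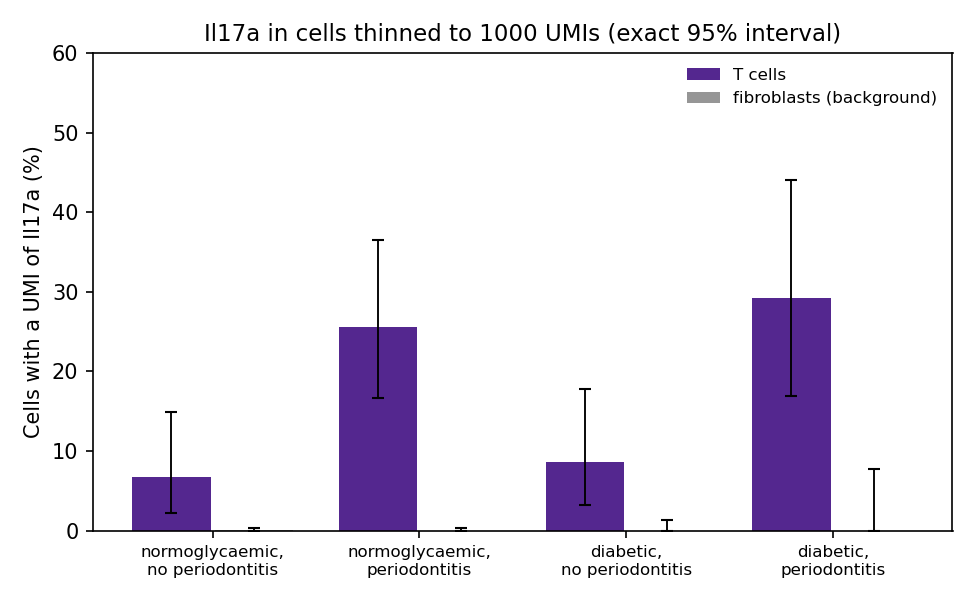
Bars give the share (%) of T cells and of fibroblasts with a UMI of Il17a in each library after thinning to 1000 UMIs per cell, with exact 95% binomial intervals. T cells stood at 6.67% and 8.57% without periodontitis and at 25.6% and 29.2% with it.

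The difference between the periodontitis log2 ratio of diabetic rats and that of normoglycaemic rats was 0.95 for the collagen and matrix list in fibroblasts (0.98 against 0.03), and 1.51 with doublets kept and 0.78 with cells weighted equally. The diabetic ratio compares different mixes of fibroblasts. Cluster 20 held 241 of 284 cells without and 12 of 50 with periodontitis. No fibroblast cluster had at least 25 cells in both diabetic libraries, so this ratio was not checked within a single cluster. For cytokines and chemokines in myeloid cells the difference was 1.14 (0.30 against -0.84), but 0.14 with no filter on low counts, 0.53 under the stricter filter, 0.61 with doublets kept and 1.84 with at least 200 UMIs per gene. With 1 library per group neither difference could be tested.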

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

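Of the tests in this part, those of the smaller stromal share and of Ada were chosen after the result was seen. The tests of Dbp were chosen before their own values were seen, but they take the higher Dbp as given. With 1 library per group, no difference between the diabetic and the normoglycaemic periodontitis ratio was tested.

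Among 235 pairs of a gene list and a cell class, 5 had periodontitis ratios of opposite sign in normoglycaemic and diabetic rats, each median at least 0.3 in size and each counting interval clear of 0. One of these, MHC class II in myeloid cells, had medians of 0.47 and -0.61, an untested difference of -1.08. It was set apart because 5 of its 6 genes are among those that define that cluster, although the list belongs to the class it was measured in. The pericyte and contractile list in blood endothelial cells had medians of -0.67 and 0.67, a difference of 1.34 that was not tested. The epithelial cornified list in mural cells had medians of 0.38 and -0.69, a difference of -1.07 that was not tested. In myeloid cells the epithelial cornified list had medians of 1.24 and -0.79, an untested difference of -2.03. In T cells the epithelial wound and defence list had medians of -0.97 and 1.37, an untested difference of 2.34. These other 4 lists belong to cell types other than the class they were measured in, and each has at least 1 median whose sign reversed under another setting.

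The clock output gene Dbp was 12.1-fold higher in epithelial cluster 0 of the diabetic periodontitis library than in that of the periodontitis library. After every cell was thinned to 1000 UMIs the log2 ratio was 2.55 (2.02 to 3.08), above the bound of 1 set for an effect of depth. Thinning keeps the expected share of a gene among a cell's UMIs, so it cannot decide whether depth played a part. A different time of day at tissue collection stays open: over 8 cell groups, the median of the clock output genes with enough UMIs (6 to 9 of 10) less that of the opposite phase genes (4 or 5 of 5) averaged 1.04 and was positive in all 8 (0.42 to 1.49). Only 4 of the 8 passed both bounds set for that explanation, and the average was 0.76 for diabetes without periodontitis and 0.02 for periodontitis in normoglycaemic rats. The time of collection was not used here, so a clock phase that may differ with diabetes and one that may differ with the hour of sampling cannot be told apart.

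Stromal and vascular cells were 28.4% of the control library and 5.66% of the diabetic library. The doublet removal is argued against as the cause, since the ratio of shares was 0.225 with doublets kept. The ratio was no higher with the stricter filter, but a stricter filter cannot return cells that the base filter removed. No looser filter was run, so the cell filter as a cause was not tested. One uniform loss of connective tissue from the piece or the digest stays open. The fibroblast ratio (0.144, 0.126 to 0.163) was 0.457 of the blood endothelial ratio (0.314, 0.272 to 0.363), and with periodontitis those ratios were 0.0576 and 0.247, but these intervals cover counting error only and the spread of class shares between pools was not measured. Within fibroblasts the fall was uneven in these libraries. Control and diabetic cells numbered 238 and 241 in cluster 20, 1243 and 19 in cluster 7, and 456 and 19 in cluster 17. The clusters were made without correction between libraries. A uniform loss and a loss that differs between cell types, through digestion or through diabetes, therefore cannot be told apart.

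Ada was 45.2-fold to 57.3-fold higher in epithelial clusters 0, 1, 2 and 3 of the diabetic library than of the control library. Free RNA is a candidate source: the median Ada level of the classes that are not epithelial was 160% of that in epithelial cluster 0, and the 7 such classes all lay above it beyond their counting intervals. An equal amount of free RNA per cell gives a higher CPM in a class with fewer UMIs per cell. In the diabetic library cluster 0 had 26281564 UMIs in 3129 cells, and fibroblasts 1393274 in 284. The comparison therefore cannot decide whether all epithelial cells also responded. Ada stood at 11333 CPM in epithelial cluster 16 and 4789 CPM in cluster 13 of the diabetic library, which may be where the free RNA came from. A response within those clusters was not tested. Cluster 13, with Ada and Krt13 among its 10 defining genes, held 1 control cell and 1099 diabetic cells, so it could not be compared.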

How the results depend on the processing

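Settings that use a single cluster of a class, and the T cell shares without thinning, were chosen after seeing the data, and the other settings before. Over all settings, class shares gave 200 values, of which 160 stayed within the interval and 40 moved. List medians gave 1330 values (849 within the interval, 456 moved, 25 reversed) and named genes 1957 (1141, 795 and 21). The Il17a shares gave 24 values, and all 24 stayed within their intervals. The interferon response median of blood endothelial cells ranged from -0.999 to -0.34 for diabetes without periodontitis and from -1.69 to -0.72 for diabetes with periodontitis. In mural cells the collagen and matrix median ranged from 0.46 to 1.04 for periodontitis in normoglycaemic rats and from 1.00 to 2.28 in diabetic rats. Centring genes within each library gave no value for epithelial clusters 0, 1 and 3, which had no matching cluster, and for cluster 2 only values for periodontitis in normoglycaemic rats. The cause of the differences listed here was not tested.

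With doublets kept, leukocytes were 2.88% of the periodontitis, 2.42% of the diabetic and 8.21% of the diabetic periodontitis library, where neutrophils were 6.19%. Myeloid cells were 0.853%, 0.849%, 0.955% and 1.44% in the 4 libraries, and T cells 0.282% in the control library. In the control, periodontitis and diabetic libraries fibroblasts were 13.9%, 8.59% and 2.59%, blood endothelial cells 8.18%, 8.31% and 2.38%, and mural cells 3.35%, 2.87% and 1.04%. Under the stricter cell filter myeloid cells were 0.902% of the control, 0.749% of the periodontitis and 0.877% of the diabetic library, T cells 0.239% and 0.536%, and blood endothelial cells 5.71% of the periodontitis and 1.26% of the diabetic periodontitis library. Schwann and glial cells were then 1.48%, 0.607%, 0.202% and 0.0129%. At resolution 2 leukocytes were 0.934% and T cells 0.277% of the control library, and blood endothelial cells 5.79%, 6.19% and 1.42% of the control, periodontitis and diabetic periodontitis libraries.

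The collagen and matrix median in fibroblasts, for periodontitis in normoglycaemic rats, was 0.14 with median-of-ratios size factors, 0.10 in cluster 17 alone and -0.36 in cluster 20 alone. For periodontitis in diabetic rats it was 1.56 with doublets kept and 0.82 with cells weighted equally, and the difference between diabetic and normoglycaemic rats 1.51 and 0.78. No fibroblast cluster had at least 25 cells in both diabetic libraries, so neither was checked within a single cluster. For diabetes without periodontitis the median was -0.70 with doublets kept and reversed to 0.071 in cluster 20 alone. For diabetes with periodontitis it was 0.51 with size factors and 0.26 in cluster 17 alone.

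The cytokines and chemokines median in myeloid cells depended on the cell filter, doublets, thinning, the weight of cells and the filter on low counts. For periodontitis in normoglycaemic rats it was -0.18 under the stricter filter, -0.28 with doublets kept, -0.33 with cells thinned and -0.059 with no filter on low counts. In diabetic rats it was 0.084 with no filter on low counts and 1.24 with at least 200 UMIs. For diabetes without periodontitis it reversed to 0.019 under the stricter filter and was -0.094 with doublets kept, -1.63 thinned, -1.72 with cells weighted equally, -0.16 with no filter on low counts and -0.84 with at least 200 UMIs. For diabetes with periodontitis these were 0.99 (stricter), 0.51 (doublets), 0.048 (thinned), 0 (no filter on low counts) and 1.28 (at least 200 UMIs). The difference between diabetic and normoglycaemic rats was 0.53 (stricter), 0.61 (doublets), 0.14 (no filter on low counts) and 1.84 (at least 200 UMIs).

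Values below are log2 ratios that reversed. With doublets kept, for diabetes without periodontitis these were interferon response in fibroblasts (-0.18), Mrc1 (0.031) and Cxcl2 (0.067) in myeloid cells and Krt10 in epithelial cluster 10 (0.18). Others with doublets kept were Krt10 in blood endothelial cells for diabetes with periodontitis (-0.41) and G2M phase in mural cells for periodontitis in diabetic rats (-0.20). For periodontitis in normoglycaemic rats, epithelial cornified in mural (-0.25) and myeloid cells (-0.19) and epithelial wound and defence in T cells (0.36) reversed with doublets kept, and in diabetic rats epithelial cornified in myeloid cells (1.44). The stricter filter reversed Mrc1 (0.28) and Cxcl2 (0.36) in myeloid cells for diabetes without periodontitis, Krt13 in epithelial cluster 3 for periodontitis in diabetic rats (-0.19) and epithelial cornified in myeloid cells for periodontitis in normoglycaemic rats (-0.46).

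The dissociation and immediate early median in epithelial cluster 10 for diabetes without periodontitis was 0.36 with doublets kept and 0.34 at resolution 2. At resolution 2, epithelial cluster 10 had Scgb1a1 at -0.15 for periodontitis in normoglycaemic rats and 0.49 for diabetes with periodontitis, S100a8 at 0.82 for the latter, Cxcl1 at 0.13 for diabetes without periodontitis and Mmp12 at 0.013 for periodontitis in diabetic rats. That resolution also reversed Krt42 in cluster 0 (0.29) and Serpinb12 in cluster 3 (-0.032) for diabetes with periodontitis, and epithelial wound and defence in T cells for periodontitis in normoglycaemic rats (0.23). Free RNA subtracted reversed, for periodontitis in diabetic rats, epithelial wound and defence in clusters 1 (-0.23) and 2 (-0.092) and Krt16 in clusters 0 (-1.26) and 2 (-0.68), and, in normoglycaemic rats, epithelial cornified in mural cells (-0.55). The latter was also -0.032 with cells thinned and -0.61 in mural cluster 24 alone. No filter on low counts put epithelial wound and defence in cluster 2 at -0.00030 for periodontitis in normoglycaemic rats.

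In blood endothelial cells the S phase list for diabetes with periodontitis was -0.53 with cells thinned and -0.015 with cells weighted equally. With cells weighted equally, Krt10 in blood endothelial cells was -0.20 for diabetes with periodontitis, and pericyte and contractile in those cells -0.23 for periodontitis in diabetic rats. Endothelial cluster 6 alone gave -0.74 and -0.21 for these, -0.039 for Icam1 in diabetic rats, -0.43 for C1qtnf9 for diabetes without periodontitis, and -0.59 and -0.022 for collagen and matrix in blood endothelial cells for periodontitis in diabetic rats and diabetes with periodontitis. Fibroblast cluster 20 alone gave -0.46 for Postn for periodontitis in normoglycaemic rats and -0.26 for interferon response for diabetes without periodontitis. Depth limits the classes with few cells: the diabetic periodontitis library holds 50 fibroblasts and 50 T cells, and the control library 21 neutrophils.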

Other observations

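The values in this part were chosen after the data were seen, and no test beyond their settings was run on them.

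Vascular cells of the diabetic periodontitis library carried more G2M phase transcripts than those of either library it was compared with. In blood endothelial cells Mki67 stood at 104 CPM against 23.1 CPM in the diabetic and 24.7 CPM in the periodontitis library, ratios of 4.50 (3.06 to 6.81) and 4.21 (3.19 to 5.58), and Top2a was 4.34-fold and 5.14-fold higher. The G2M phase list had medians of 1.54 (9 of 9 genes at least 1.5-fold higher) and 1.43 (10 of 10) there, and of 0.51 and 0.64 with cells weighted equally. The S phase list had medians of 0.20 (-0.12 to 0.37) and 0.40 (0.15 to 0.55) in the same cells, and with cells thinned of -1.24 and -0.53, so a difference in the whole cell cycle is not shown. Mural cells had Mki67 at 80.2 CPM against 22.9 CPM and 22.5 CPM, and G2M phase medians of 1.74 (6 of 7 genes) and 1.47 (7 of 7), the former reversing to -0.20 with doublets kept. For periodontitis in normoglycaemic rats the G2M phase median in blood endothelial cells was 0.11 (-0.09 to 0.27). Whether these transcripts come from dividing vascular cells or from free RNA and doublets with cycling epithelial cells was not tested beyond the settings named.

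The collagen and matrix list in blood endothelial cells of the diabetic periodontitis library had medians of 0.92 against the diabetic library and 1.34 against the periodontitis library. In cluster 6 alone, the larger endothelial cluster, these reversed to -0.59 and -0.022.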
